A study of Mus musculus with 6 samples.

How the data were processed

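RNA was taken from cryosections of mouse testis, with 3 WT and 3 H3t deletion samples, and each gave 1 library made with a stranded SMART-Seq kit, per the labels' protocols. The deposited table holds raw counts of reads per Ensembl gene, which were made by trimming with Trim Galore, mapping to GRCm38 with HISAT2 and counting with featureCounts, per the submitters' processing notes. Versions, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes, such as H3f4 and Trim17, cannot be assigned with certainty. The spatial data that the series mentions were not analysed here. The table has 54100 genes, 0 of them without a name, and 0 columns of per-sample values were left unused. All 54100 Ensembl genes, with the same chromosomes, are in GENCODE M21, from which 1-based GRCm38 coordinates and transcript sequences were taken. The share of 50-mers that a gene's transcripts have in common with other genes marks genes whose reads the counting could not place uniquely.

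Libraries were grouped by genotype as the labels give it. The labels do not say that each came from a separate mouse beyond a number in the title, so p-values measure the spread between these samples, which may be partly technical. No 2 libraries agreed within sampling noise, with a chi-square per degree of freedom of 4.48 to 6.88 within groups. Totals ran from 8037826 to 10702930, and 1 count was worth 0.0904 to 0.156 CPM. For a gene at 0 counts in every library of a group, a floor of 3 counts over the group, 0.0926 CPM in the deletion and 0.136 CPM in WT, gives the bound written as at least N-fold. Floors cover counting error only.

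Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which left 17038, libraries were scaled by TMM, and the deletion was compared with WT by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at a false discovery rate of 0.05. The biological coefficient of variation was 13.1%. TMM factors were 0.794 to 0.806 in WT and 1.21 to 1.27 in the deletion. CPM values are TMM-scaled, and log2 fold changes are deletion minus WT as fitted by edgeR's test at its default settings. A prior count of 2 entered the log2 CPM values used for correlations, list tests and list scores, and not the fold changes. Shares of counts and other values per library were compared by exact two-sided permutation tests.

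Before the data were examined, 33 gene lists were fixed for testis cell types, steroid and sterol synthesis, stress, growth, the cell cycle, mitochondria and histone variants, and 31 of them had the 3 tested members needed for a list test. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Of the 22 lists called, 19 were higher and 3 lower, and 0 passed with the correlation estimated per list, at adjusted p-values of 0.128 to 0.315. Counts of members adjusted over the list alone differed from those over all genes in 1 list. A list score is the mean log2 CPM of a list's tested members in a library.

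Genes were named by a rule written before the data were examined. It takes H3f4 and a fixed set of testis, steroid and stress genes. It adds the 8 largest gains and the 8 largest losses among called genes with a mean of at least 10 CPM, no overlap between the groups and a symbol that is no clone name. It further adds from each list up to 3 called members with the highest mean CPM, or the most abundant member where none was called. Some genes that the rule or a list count would name are not reported here. Chosen after their values were seen were Lipe, Acbd3, Smpdl3a, Cyp19a1, Sqle, Pi16, Mfap5, Pln, Prox1, Sox17, Tex11, Dhx58, Jag1, Pdgfa, Postn, Adipoq, Krt8, Krt18, Trib3, Atf3, Gadd45a, Ccnd1, Ccnd2, Malat1, Hspb8, Socs3, Timp1, Wnt4, Hrk, Ptpn5 and Trim17.

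The same steps were tested on simulated counts with 15432 genes. Both groups were drawn from the WT profile, and few genes were changed, up and down in equal number. Of genes changed 1.5-fold, 2-fold and 4-fold, 34.4% of 61, 72.9% of 59 and 93.4% of 61 were recovered, with 5 false calls, 3.97% of all calls. In the real data 84.5% of the genes were called and TMM factors differed between the groups. The simulated rates were not tested for a shift of that size. With a simulated shift of the steroidogenesis list, 1 of 30 lists tested was called, the steroidogenesis list itself. The other lists were left unchanged and genes were drawn independently, so correlation within lists was not covered. Alternatives were other scalings, including an equal level of the Sertoli or Leydig identity list in every library, other filters, a false discovery rate of 0.01, a test against a 1.5-fold change, DESeq2 1.42.0, limma voom, each library left out in turn, a block of adjacent mouse numbers, and other list tests, backgrounds and list scores.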

Results

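Bulk RNA-seq libraries were made from cryosections of mouse testis. The 6 libraries fell into 2 groups, 3 from wild-type (WT) mice and 3 from mice with a deletion of H3t, a histone H3 variant of the testis. The series concerns Leydig cells, the testosterone-producing cells between the seminiferous tubules, in testes where spermatogenesis fails, and its title speaks of stress, proliferation and testosterone synthesis. The comparison of the 2 groups asked which genes differed between these testes, and how Leydig cell, steroid synthesis, stress and cell cycle genes stood among them. Total counts were 8037826, 10702930 and 8965924 in WT replicates 1, 2 and 3 and 8988520, 8746636 and 8315960 in deletion replicates 1, 2 and 3, and an exact two-sided permutation test of the group difference gave p = 0.8. With 3 libraries per group the smallest p such a test can give is 0.1, so exact tests of single values cannot pass 0.05 here. Across genes, log2 CPM values correlated at r = 0.976 to 0.983 within groups and at 0.379 to 0.43 between them.

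The targeted gene was counted in WT only. H3f4, the current symbol of H3t (ENSMUSG00000080152, GRCm38 chromosome 11, 58961812 to 58962222, plus strand, a locus that the table types as an unprocessed pseudogene), had 390, 571 and 356 counts in WT replicates 1, 2 and 3 and 0 counts in each of the 3 H3t deletion libraries. Its WT level was 59.1 ± 8.22 CPM (SD, n = 3), which makes it at least 639-fold lower in the deletion when 3 counts over the deletion libraries are taken as the floor. The difference had an adjusted p of 4.98e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. H3f4 lies inside the annotated span of Trim17, so reads of the 2 genes can be told apart only as far as the counting allowed.

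**Figure D1:**
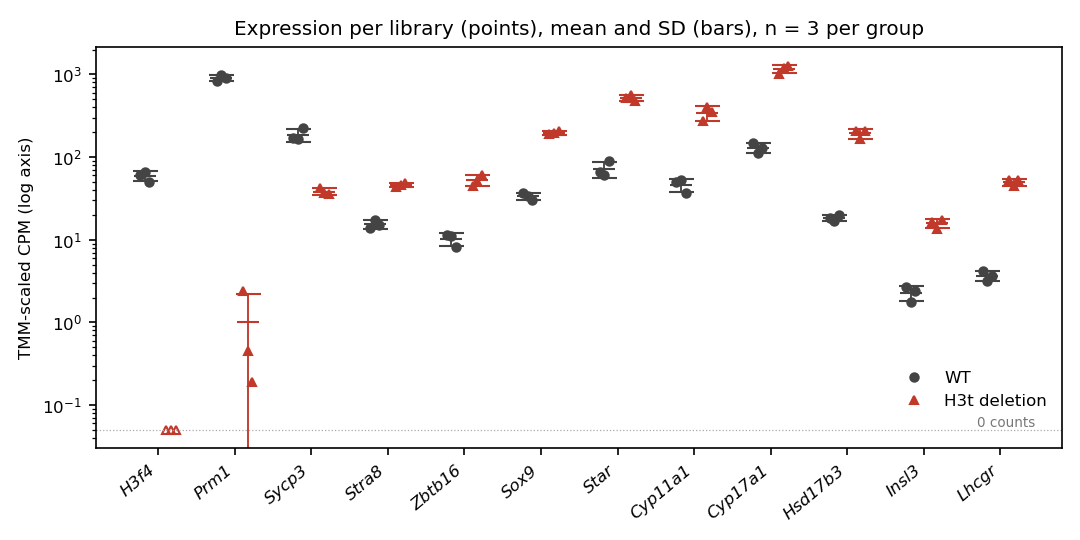
Expression of 12 genes per library, in TMM-scaled CPM on a log axis, for WT (circles) and H3t deletion (triangles), with the mean and SD of 3 libraries. H3f4 sits at 59.1 CPM in WT and has 0 counts in the deletion (open triangles on the dotted line), the spermatid gene Prm1 falls from 908 to 1.01 CPM, where the lower SD bar leaves the axis, and the steroid genes Star, Cyp11a1, Cyp17a1 and Hsd17b3 are higher in every deletion library than in any WT library.

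Most of the transcriptome differed between the groups. Spermatid genes such as Prm1 and Prm2 were nearly gone, genes of spermatocytes were much lower, and genes of Leydig cells, Sertoli cells and macrophages were several-fold higher with TMM scaling. Of 17038 genes tested, 6542 were higher and 7861 lower in the deletion at a false discovery rate of 0.05. At least 8-fold changes were mostly losses, with 589 genes higher and 4040 lower. At least 100-fold changes numbered 3 higher and 1566 lower. In these counts a gene at 0 counts in a group was taken at its bound. The groups did not overlap for 85.9% of the genes, where chance gives 10%. The largest losses by the naming rule were Prss37, Lrrc43, Kcne3, Hyal5, St8sia3, Trp53tg5, Ftmt and Rfx4, all at 0 counts in the deletion and at least 861-fold (Rfx4) to at least 1333-fold (Prss37) lower. The largest gains were Wfdc18, with 0 counts in WT and 49.5 ± 2.33 CPM in the deletion (SD, n = 3, at least 365-fold higher), and, with log2 changes of 5.24 to 4.23, Serpina3n, Ildr2, Il17rb, H2-Aa, Armcx6, Klk1b24 and Igfbp3. Of these, 33.9% of the 50-mers of Klk1b24 are shared with other genes, and Armcx6 went from 4.35 to 5.04 without WT replicate 3.

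The direction of a change rests on the scaling, because so much of the RNA differed. The median log2 change over all genes was -0.19 with TMM, -0.36 with median-of-ratios, 0.35 with upper-quartile and 0.45 with no scaling factor, and higher calls made up 45.4%, 42.3%, 55.1% and 56.6% of all calls. When libraries were instead scaled to an equal level of the Sertoli list, 463 genes were higher and 13313 lower, with a median of -2.51. Scaled to an equal level of the Leydig identity list, 154 were higher and 14743 lower, with a median of -3.0. These last scalings, called Sertoli-level and Leydig-level scaling from here on, ask whether a gene changed relative to those cells' genes, and both are given beside list medians that lay above 0 with TMM. The share of mitochondrial counts was 5.98% ± 0.429 in WT and 22.1% ± 0.566 in the deletion (SD, n = 3). That of Malat1, a nuclear long noncoding RNA, was 0.207% ± 0.00577 and 2.13% ± 0.554. That of the 10 most abundant genes was 8.91% ± 0.445 and 24.5% ± 0.17. Each gave an exact permutation p of 0.1, the smallest possible.

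Spermatid and meiotic genes fell. All 39 tested members of the spermatid list fell, with a median log2 change of -9.01, and their share of all counts was 2.79% ± 0.04 in WT and 0.0233% ± 0.00577 in the deletion (SD, n = 3). Prm1, a protamine that packs sperm DNA, went from 908 ± 72.1 to 1.01 ± 1.20 CPM, and Prm2, Tnp2 and Smcp fell, with log2 changes of -9.53, -9.54 and -9.62. Deletion replicate 1 held 26 of the counts of Prm1 in the deletion and replicates 2 and 3 held 5 and 2, and without replicate 1 the log2 changes of Prm1, Prm2, Tnp2 and Smcp were -11.38, -10.74, -10.56 and -10.61. Of 38 meiotic prophase genes 35 fell and 1 rose, with a median of -2.98. Ldhc, the testis lactate dehydrogenase, was at -9.54, Hspa2 at -5.08, Smc1b at -2.91 and Sycp3, of the synaptonemal complex, at -2.28. The X-linked Tex11, named after its value was seen, rose by 0.45. Camera's adjusted p was 6.20e-09 for the spermatid and 1.79e-06 for the meiotic list, and 0.218 and 0.142 with an estimated correlation.

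Spermatogonial lists were mixed. Of 14 undifferentiated spermatogonial genes 9 rose and 1 fell, with a median of 1.69 that became -0.60 and -1.12 at Sertoli and Leydig level (camera adjusted p = 0.0181, and 0.260 with an estimated correlation). Zbtb16, a transcription factor of these cells, rose from 10.2 ± 1.76 to 52.4 ± 8.07 CPM (SD, n = 3), Etv5, with 24.5% of its 50-mers shared, rose by 1.78, and Id4 fell by 1.41. Of 21 differentiating spermatogonial genes 6 rose and 11 fell with TMM, against 9 and 8 with upper-quartile and 10 and 6 with no scaling. Their median was -0.55, or 0.09 without a scaling factor, and the list test did not pass (camera adjusted p = 0.677). Stra8, which marks entry into meiosis, rose by 1.58 and Kit, which Leydig cells express too, by 3.13, whereas Ddx4, Mael and Dmrtb1 fell, to log2 changes of -4.16, -5.22 and -6.21.

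**Figure D2:**
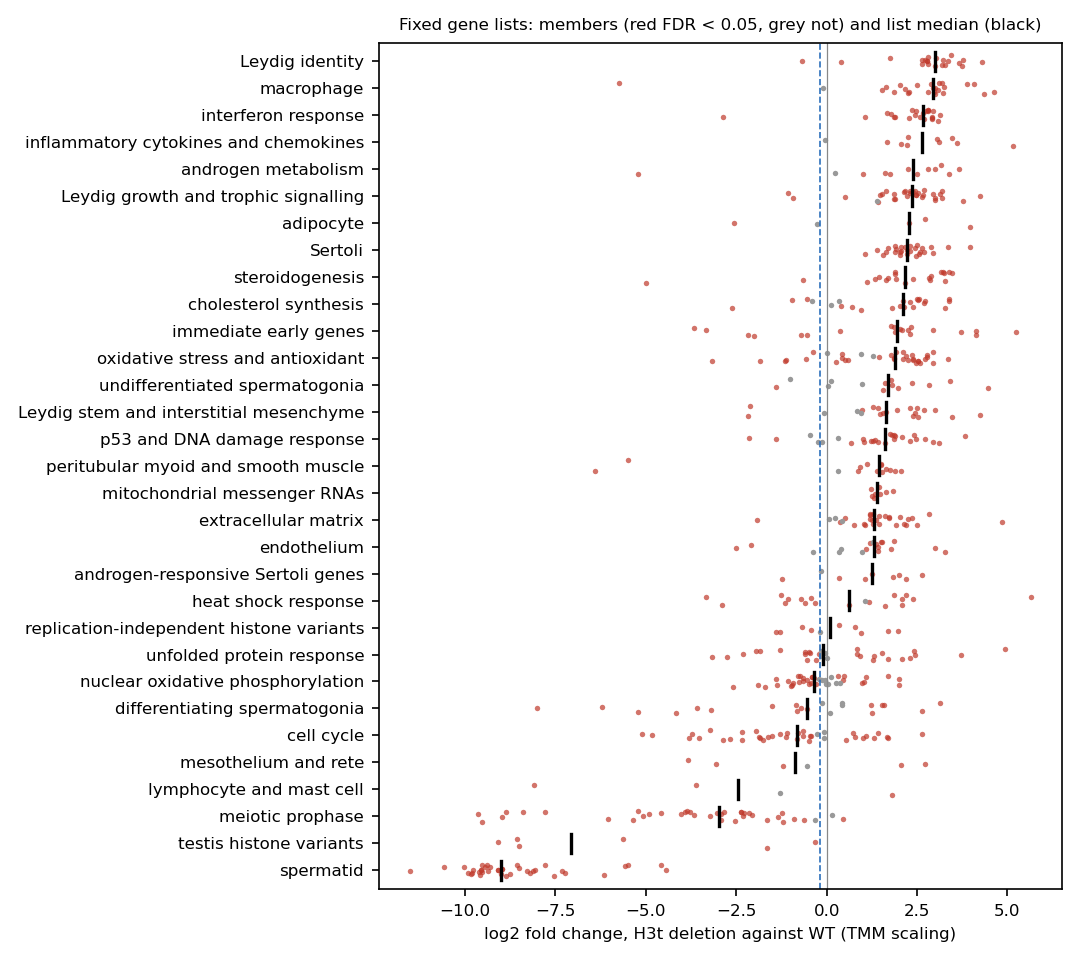
Log2 fold changes of the tested members of each fixed gene list with 3 or more of them, H3t deletion against WT, with members past FDR 0.05 in red, the others in grey, the list median as a black bar and the median of all genes as a dashed line. Medians run from -9.01 for the spermatid list to 3.0 for the Leydig identity list with TMM scaling; at Sertoli or Leydig level most of the medians above 0 turn negative.

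Genes of steroid synthesis rose together with TMM scaling. Of 21 tested members 19 rose and 2 fell, with a median log2 change of 2.16 that became -0.17 and -0.65 at Sertoli and Leydig level. Star (chromosome 8, 25806555 to 25815982), which carries cholesterol into mitochondria, rose from 71.5 ± 15.2 to 519.5 ± 42.0 CPM, and Cyp11a1 (chromosome 9, 58006411 to 58027023), which makes pregnenolone there, from 46.2 ± 8.51 to 343 ± 67.3 CPM (SD, n = 3). Cyp17a1 (chromosome 19, 46667165 to 46673172) rose from 129.9 ± 19 to 1159 ± 133 CPM and Hsd17b3 (chromosome 13, 64058266 to 64089230), which makes testosterone from androstenedione, from 18.5 ± 1.45 to 193 ± 25.6 CPM. The log2 changes of Star, Cyp11a1, Cyp17a1 and Hsd17b3 were 2.86, 2.89, 3.16 and 3.39, with standard errors of 0.13, 0.15, 0.12 and 0.13 and adjusted p-values of 9.28e-12, 7.31e-11, 1.44e-12 and 8.61e-13 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). At Leydig level Star and Cyp11a1 were at 0.06 and 0.07 and no longer called. Hsd3b1 rose by 3.48, Hsd3b6 by 3.21, with 15.6% of its 50-mers shared with other genes, and the cholesterol transporter Abca1 by 3.24. The members that fell, named after their values were seen, were Lipe, the hormone-sensitive lipase, at -5.00, and Acbd3 at -0.65. Camera's adjusted p for the list was 5.35e-06, and 0.128 with an estimated correlation.

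Leydig cell genes outside the steroid pathway rose too. Of 21 members of the Leydig identity list 20 rose and 1, Smpdl3a, fell, with a median of 3.0 that was 0.68 at Sertoli and 0.18 at Leydig level. Lhcgr, the receptor for luteinizing hormone (chromosome 17, 88716481 to 88791990), rose from 3.67 ± 0.532 to 49.8 ± 4.52 CPM, Insl3, a Leydig cell hormone, from 2.26 ± 0.466 to 15.7 ± 1.89 CPM, and Ptgds from 95.8 ± 9.47 to 1270.0 ± 203 CPM (SD, n = 3). Aldh1a1 rose by 2.78 and Gramd1b by 0.41. Camera's adjusted p was 3.38e-07, and 0.128 with an estimated correlation. Of 12 androgen metabolism genes 10 rose, among them Sult1e1, Hsd17b12 and Hsd17b4 at 3.66, 2.81 and 1.0, and 1 fell, the aromatase Cyp19a1 at -5.22, or -6.38 without deletion replicate 1. Their median was 2.38, and 0.07 and -0.44 at Sertoli and Leydig level (camera adjusted p = 0.00134, and 0.128 with an estimated correlation). Bulk tissue does not tell which cells gave the WT counts of Cyp19a1 or Lipe. Of 23 cholesterol synthesis genes 17 rose and 3 fell, with a median of 2.12 that became -0.20 and -0.69 at Sertoli and Leydig level (camera adjusted p = 0.000771, and 0.142 with an estimated correlation). Msmo1 and Hmgcs1 rose by 3.37 and 2.14, while Fdft1 and Sqle were at -2.63 and -0.55, with Sqle at 0.08 without a scaling factor.

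Within libraries, where no scaling factor enters, Leydig and Sertoli genes moved apart. The mean log2 CPM of the Leydig identity list minus that of the Sertoli list was 0.06 ± 0.16 in WT and 0.61 ± 0.08 in the deletion (SD, n = 3), a gain of 0.55. The steroidogenesis list minus the Sertoli list went from 1.1 ± 0.15 to 0.81 ± 0.08, a difference of -0.29, and the steroidogenesis list minus the Leydig identity list from 1.05 ± 0.05 to 0.20 ± 0.11, a difference of -0.84. In all 3 cases the 6 libraries separated by group, which gives an exact two-sided permutation p of 0.1, the smallest possible, and 0.113 adjusted over 9 such differences. With the median log2 CPM of the members as the score, the differences were 0.35 for Leydig identity against Sertoli and -1.15 for steroidogenesis against Sertoli. For steroidogenesis against Leydig identity it was -1.50. Such a score follows the level of the middle member, not the median change of the members. Median log2 changes with TMM were 3.0 for Leydig identity, 2.22 for Sertoli and 2.16 for steroidogenesis. Lipe, at -5.00, weighed on the steroidogenesis mean: without it, a check chosen after seeing the data, the difference to the Sertoli list was 0.06 and that to the Leydig identity list -0.50. With TMM the mean log2 change was 1.92 over the steroidogenesis list and 2.79 over the Leydig identity list. Star, Cyp11a1, Hsd3b1, Hsd3b6, Cyp17a1 and Hsd17b3 were at 2.86, 2.89, 3.48, 3.21, 3.16 and 3.39. The lower list score therefore does not describe these genes. Further differences were chosen after seeing the data. Against the Sertoli list the endothelial list moved by -1.24, the myoid list by -1.74 and the mesenchymal list by -0.54, and the Leydig identity list moved by 1.80 against the endothelial and the macrophage list by -0.50 against the Leydig identity list (exact two-sided permutation p = 0.1 each, the smallest possible). The macrophage list against the Sertoli list was at -1.90 ± 0.15 in WT and -1.84 ± 0.37 in the deletion (SD, n = 3, exact permutation p = 1).

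Genes of other somatic cell types rose with TMM scaling. All 28 Sertoli genes rose, with a median of 2.22 that became -0.09 and -0.59 at Sertoli and Leydig level, and Clu, Aard and Ctsl were at 2.30, 2.03 and 1.64. Sox9, which sets Sertoli cell fate, went from 33.5 ± 3.06 to 197 ± 10.4 CPM (SD, n = 3). Of 9 androgen-responsive Sertoli genes 7 rose, such as Myo6 by 1.83, and 1 fell, Ube2b, which germ cells also use, at -1.23. Their median was 1.25, and -1.05 and -1.57 at Sertoli and Leydig level. Of 21 genes of stem Leydig cells and interstitial mesenchyme 16 rose, among them Pdgfra, Lifr and Dcn at 3.0, 2.45 and 1.95, and Pi16 and Mfap5 fell. The median was 1.63, and -0.68 and -1.19 at Sertoli and Leydig level. Of 14 myoid and smooth muscle genes 11 rose, such as Myh11 and Mylk at 1.51 and 0.92, but Actg2 and Pln were at -5.49 and -6.41, Pln at -8.80 without deletion replicate 1 (median 1.45, and -0.87 and -1.37 at Sertoli and Leydig level). Which cells gave the WT counts of Actg2 and Pln was not tested. Of 18 endothelial genes 11 rose, such as Kdr, Cdh5 and Ptprb at 1.78, 1.5 and 1.08, and Sox17 and Prox1 fell (median 1.32, and -0.95 and -1.48). Of 30 extracellular matrix genes 26 rose, such as Timp3, Sparc and Col1a2 at 2.26, 2.20 and 1.45, and 1, Postn, fell (median 1.32, and -0.99 and -1.49). The camera adjusted p-values of these lists, in this order, were 3.84e-09, 0.0233, 0.000206, 0.00806, 0.0263 and 6.69e-07, and with an estimated correlation the adjusted p-values were 0.142, 0.155, 0.128, 0.174, 0.190 and 0.128.

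Macrophage and interferon genes rose, unevenly across the deletion libraries. Of 25 macrophage genes 23 rose, Mpeg1 by 2.96 and the mannose receptor Mrc1 by 1.85, and 1, Aif1, fell by 5.74, with a median of 2.93 (0.62 and 0.12 at Sertoli and Leydig level, camera adjusted p = 1.85e-05, and 0.196 with an estimated correlation). Which cells gave the WT counts of Aif1 was not tested. Of 23 interferon response genes 22 rose and 1, Dhx58, fell, with a median of 2.66 that was 0.38 and -0.15 at Sertoli and Leydig level (camera adjusted p = 5.41e-05, and 0.315 with an estimated correlation). The MHC genes stood apart in deletion replicate 1: B2m was at 269, 109.6 and 119 CPM in deletion replicates 1, 2 and 3 against 15.9, 26.9 and 21.4 CPM in WT, and H2-Aa, of MHC class II, at 44.8, 8.59 and 11.2 CPM against 0.467, 1.51 and 0.987 CPM. Without that replicate the log2 changes of H2-Aa, B2m, H2-D1 and H2-K1 went from 4.36, 2.94, 2.66 and 1.87 to 3.26, 2.41, 2.24 and 1.47. Of 10 inflammatory cytokine and chemokine genes 9 rose, among them Cxcl12, Csf1 and Nfkbia at 3.46, 3.05 and 2.21 (median 2.65, and 0.33 and -0.16 at Sertoli and Leydig level; camera adjusted p = 0.00206, and 0.212 with an estimated correlation). Of 4 lymphocyte and mast cell genes 1 rose, Cd4 at 1.82, and 2 fell, Cd8b1 at -3.60, or -4.46 without deletion replicate 2, and Cd3d, which had 0 counts in the deletion and was at least 40.2-fold lower (camera adjusted p = 0.545). Leaving out WT replicate 2, WT replicate 3 or deletion replicate 1 ended the call of Cd4, at 1.84, 1.39 and 0.85.

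Of the stress lists, the oxidative stress, p53 and immediate early lists held more members that rose than fell with TMM scaling. The unfolded protein and heat shock lists held as many of each with TMM, and more that rose with upper-quartile and no scaling. Of 36 oxidative stress and antioxidant genes 27 rose and 6 fell, or 28 and 6 when adjusted over the list alone, with a median of 1.89 that became -0.39 and -0.92 at Sertoli and Leydig level (camera adjusted p = 2.63e-05, and 0.128 with an estimated correlation). The glutathione transferases Gstm1 and Gstm2 rose by 2.93 and 2.77, with 18.9% of the 50-mers of Gstm1 shared with other genes, and Sod1 rose by 0.51. Hmox1, a heme oxygenase induced by oxidative stress, went from 4.89 ± 2.54 to 19.05 ± 1.85 CPM (SD, n = 3). Of 27 genes of the p53 and DNA damage response 21 rose and 2, Mdm2 and Polk, fell by 2.16 and 1.41, with a median of 1.6 (-0.74 and -1.22 at Sertoli and Leydig level; camera adjusted p = 0.00091, and 0.128 with an estimated correlation). Cdkn1a, a cell cycle inhibitor, rose by 1.43, Sesn1 by 1.80 and Gadd45a, chosen after its value was seen, by 3.83. In the unfolded protein response 13 of 30 genes rose and 13 fell with TMM. These counts were 13 and 15 with median-of-ratios, 19 and 6 with upper-quartile and 20 and 6 with no scaling. The median was -0.10, or 0.44 and 0.54 with upper-quartile and no scaling. The mean was 0.32, and the list test, which pointed up, did not pass (camera adjusted p = 0.553). Hspa5, the main chaperone of the endoplasmic reticulum, was at 863 ± 56.1 and 775 ± 43.0 CPM (SD, n = 3, adjusted p = 0.113 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Pdia4 rose by 0.91, and Ddit3, a stress-induced transcription factor, fell by 1.95. Hspa5 passed without WT replicate 1, at -0.24. Calr and Hsp90b1, chaperones of the same compartment, fell by 0.54 and 0.21 with TMM but were at 0.00 and 0.33 with upper-quartile scaling, where Hspa5 was at 0.39. Hsp90b1 was no longer called without WT replicate 3, deletion replicate 2 or deletion replicate 3, at -0.20, -0.17 and -0.20. Trib3 and Atf3, named after their values were seen, rose by 4.92 and 3.72, with Trib3 at 7.92 without WT replicate 1 and both at 4.27 and 3.03 without WT replicate 2. Of 19 heat shock genes 9 rose and 9 fell with TMM, against 10 and 5 with upper-quartile and 12 and 5 with no scaling. Examples were Hsp90ab1 up by 1.18, Hspa4 at -1.15 and Hsp90aa1 at -2.90 (47.5% of its 50-mers shared), and the median was 0.61, or -1.70 and -2.20 at Sertoli and Leydig level. The list test did not pass (camera adjusted p = 0.553). Of 20 immediate early genes, which handling of tissue also induces, 14 rose and 6 fell, with Jun and Jund up by 2.30 and 0.37 and Klf4 at -3.66 (median 1.95, -0.33 and -0.84 at Sertoli and Leydig level; camera adjusted p = 0.027, and 0.155 with an estimated correlation).

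Cell cycle genes were mostly lower and growth signalling genes mostly higher. Of 39 cell cycle genes 10 rose and 26 fell, with a median of -0.83 (camera adjusted p = 0.0702). With upper-quartile scaling 11 rose and 20 fell, and the median was -0.29, and with no scaling 11 rose and 19 fell, and it was -0.19. Top2a and Cenpf, of dividing cells, fell by 1.84 and 1.95, and Mki67, the proliferation antigen, fell from 194 ± 24.6 to 138 ± 9.33 CPM (SD, n = 3), a log2 change of -0.49 that was 0.05 and 0.15 with upper-quartile and no scaling. Ccnd2 and Ccnd1, cyclins of the G1 phase named after their values were seen, rose by 2.65 and 1.42. Of 32 genes of Leydig growth and trophic signalling 29 rose, among them Prlr, Lifr and Gja1 at 3.18, 2.45 and 2.31, and Pdgfa and Jag1 fell (median 2.36, and 0.02 and -0.46 at Sertoli and Leydig level; camera adjusted p = 3.10e-08, and 0.128 with an estimated correlation).

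Mitochondrial messenger RNAs rose with TMM scaling, and the balance of nuclear genes of respiration turned with the scaling. All 8 tested mitochondrial messenger RNAs rose, mt-Cytb by 1.44, mt-Co1 by 1.25 and mt-Nd1 by 1.22, with a median of 1.39 that became -0.94 and -1.43 at Sertoli and Leydig level (camera adjusted p = 0.00025, and 0.260 with an estimated correlation). Of 39 nuclear genes of oxidative phosphorylation 9 rose and 21 fell with TMM, against 18 and 9 with upper-quartile and 18 and 8 with no scaling, with Atp5a1 at 0.31, Atp5b at -0.29 (0.26 with upper-quartile scaling) and Ndufv2 at -1.89. Their median was -0.36, or 0.18 and 0.28 with upper-quartile and no scaling, and the list test did not pass (camera adjusted p = 0.557). Of the mitochondrial members, mt-Co1 shares 51.1% of its 50-mers with other genes, and mt-Co2 had 73 counts over the 6 libraries and shares 100%.

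All 6 tested testis histone variants fell with TMM scaling, while H2ac1 was at 0.22 and 0.32 with upper-quartile and no scaling. H1f7, H1f6 and H2ac1 were at -9.09, -5.63 and -0.32, and the median was -7.07 (camera adjusted p = 0.0218, and 0.248 with an estimated correlation). Without deletion replicate 1 H1f7 was at -10.31, and without deletion replicate 3 H2ac1 was at -0.25 and no longer called. Of 10 replication-independent variants 5 rose and 4 fell with TMM. These counts were 4 and 5 with median-of-ratios and 6 and 2 with upper-quartile and with no scaling. Examples were H3f3b at -0.68, H2ax at -0.42 (0.12 with upper-quartile scaling) and H2az1, with 16.9% of its 50-mers shared, at -1.28, and the median was 0.08, or -0.09 with median-of-ratios, 0.62 with upper-quartile and 0.72 with no scaling, and -2.25 and -2.73 at Sertoli and Leydig level (camera adjusted p = 0.727). Of lists for tissue next to the testis, 3 of 5 adipocyte genes rose, Plin4, Plin1 and Lpl at 3.97, 2.73 and 2.28, and 1, Adipoq, fell by 2.56, with a median of 2.28 that was -0.02 and -0.55 at Sertoli and Leydig level (camera adjusted p = 0.304, and 0.0202 without deletion replicate 2). Adipoq was at -1.96 and -4.40 without deletion replicates 2 and 3. Lpl was at 15.9, 4.52 and 16.3 CPM in deletion replicates 1, 2 and 3. Of 6 mesothelium and rete genes 2 rose, Lrrn4 at 2.72 and Krt18 at 2.07, and 3 fell, Epcam, Muc16 and Krt8 at -1.21, -3.84 and -3.07 (camera adjusted p = 0.727). Krt18 was at 1.58 and 1.45 and no longer called without WT replicate 3 and without deletion replicate 3, and Krt8 at -3.94 without the latter. The erythroid list had 1 tested member, Alas2 at 0.26 (adjusted p = 0.248 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the epididymis list 1, Rnase10, at 0 counts in the deletion and at least 28.3-fold lower.

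X-linked genes rose relative to autosomal ones. Of 624 tested X-linked genes 411 were higher and 150 lower, against 6117 and 7701 of 16385 autosomal genes. The median log2 change was 1.59 on the X chromosome and -0.27 on the autosomes, a difference of 1.86 that no scaling factor moves (camera p = 7.07e-08, and p = 0.00409 with an estimated correlation). Single autosomes had medians from -0.57 to 0.09. X-linked genes made up 1.16% ± 0.0165 of nuclear counts in WT and 3.79% ± 0.0226 in the deletion (SD, n = 3, exact permutation p = 0.1, the smallest possible).

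**Figure D3:**
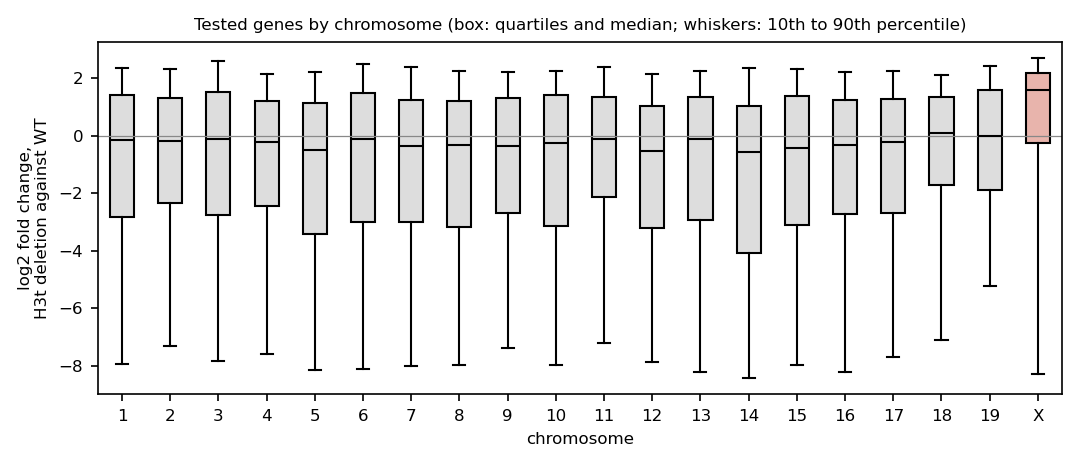
Log2 fold changes of all tested genes by chromosome, H3t deletion against WT with TMM scaling, as medians, quartiles and the 10th to 90th percentile. The X chromosome has a median of 1.59 and the autosomes lie between -0.57 and 0.09.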

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

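The checks without Lipe and with a block of adjacent mouse numbers were chosen after the result was seen, and all other alternatives before the data were examined. No paired analysis was possible because the mouse numbers in the labels are not shared between the groups. Some numbers are adjacent across the groups, WT replicate 3 with deletion replicate 1 and WT replicate 1 with deletion replicates 2 and 3, but no label ties them to a litter or batch. Over genes, the deviations of such libraries from their group means correlated at -0.01 to 0.01. With a block of adjacent numbers the genes higher in H3t deletion numbered 6074 and the genes lower in H3t deletion 7584, and Cd4, Hsp90b1, H2ac1, Adipoq and Krt18 no longer passed, at 1.71, -0.21, -0.24, -2.38 and 2.24. Of 156 named genes, 148 kept their direction with median-of-ratios, upper-quartile and no scaling. Leaving out each library in turn gave 930 values for named genes, of which 0 reversed, 9 no longer passed the threshold and 1 newly passed it. The counts of genes higher and lower ran from 6356 to 6591 and from 7899 to 8287 over these. Depth limits calls near the floor. The call of Cd4, with 84, 13 and 29 counts in deletion replicates 1, 2 and 3, rested on single libraries, and whether low counts were the cause was not tested. DESeq2 and the test against a 1.5-fold change give no list results, and DESeq2 gave no adjusted p for 1 gene. Named genes and lists that kept their direction but no longer passed numbered 15, 9, 3, 1, 3, 5, 7, 14 and 15 with the test against a 1.5-fold change, a false discovery rate of 0.01, DESeq2, limma voom, median-of-ratios scaling, upper-quartile scaling, no scaling, the Sertoli list held equal and the Leydig identity list held equal. Newly passing, in this order, were 0, 0, 1, 1, 1, 1, 2, 4 and 4. Among those lost with the Leydig identity list held equal were Star and Cyp11a1, at 0.06 and 0.07. Without genes that several lists hold, the immediate early, androgen-responsive Sertoli and testis histone lists no longer passed, at 2.06, 1.44 and -3.45 against all genes.

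With upper-quartile scaling Calr, Mki67, H2ax, H2ac1, Atp5b, Hsp90b1 and Hspa5 reversed to log2 changes of 0.00, 0.05, 0.12, 0.22, 0.26, 0.33 and 0.39. With no scaling factor Sqle, Calr, Mki67, H2ax, H2ac1, Atp5b, Hsp90b1 and Hspa5 reversed to 0.08, 0.10, 0.15, 0.22, 0.32, 0.35, 0.43 and 0.48. These scalings move the median of all genes from -0.19 to 0.35 and 0.45. The unfolded protein response list, whose median lies 0.09 above that of all genes, passed with no scaling factor at 0.09 (camera adjusted p = 0.0434), and the cause was not tested.

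With the Sertoli list held equal in every library 463 genes were higher and 13313 lower, and the list held equal sets this by construction. The log2 changes of Alas2, Atp5a1, Jund, Gramd1b, Tex11, Sod1, Pdia4, Mylk, Hsd17b4, Ptprb, Hsp90ab1, mt-Nd1, mt-Co1 and mt-Cytb became -2.04, -2.01, -1.95, -1.91, -1.88, -1.82, -1.41, -1.40, -1.31, -1.20, -1.15, -1.11, -1.08 and -0.89. Those of Col1a2, Ccnd1, Cdkn1a, Cdh5, Myh11, Stra8, Ctsl, Sesn1, Kdr, Myo6, Cd4, Etv5, Mrc1 and H2-K1 became -0.88, -0.86, -0.83, -0.83, -0.80, -0.73, -0.69, -0.55, -0.54, -0.50, -0.49, -0.49, -0.46 and -0.43. Those of Dcn, Hmox1, Aard, Krt18, Hmgcs1, Sparc, Nfkbia, Timp3, Clu, Lpl and Jun became -0.36, -0.33, -0.29, -0.23, -0.19, -0.12, -0.10, -0.07, -0.02, -0.02 and -0.01. The cell cycle list passed, at -0.62 against all genes.

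With the Leydig identity list held equal in every library 154 genes were higher and 14743 lower, and the list held equal sets this by construction. The log2 changes of Alas2, Atp5a1, Jund, Gramd1b, Tex11, Sod1, Pdia4, Mylk, Hsd17b4, Ptprb, Hsp90ab1, mt-Nd1, mt-Co1 and Ccnd1 became -2.56, -2.50, -2.45, -2.40, -2.36, -2.30, -1.91, -1.89, -1.81, -1.73, -1.64, -1.59, -1.57 and -1.40. Those of mt-Cytb, Cdkn1a, Col1a2, Cdh5, Myh11, Stra8, Ctsl, Kdr, Etv5, Sesn1, Cd4, Myo6, Mrc1 and H2-K1 became -1.38, -1.37, -1.36, -1.31, -1.30, -1.24, -1.18, -1.03, -1.03, -1.01, -0.98, -0.98, -0.96 and -0.94. Those of Hmox1, Dcn, Aard, Krt18, Hmgcs1, Sparc, Nfkbia, Timp3, Lpl, Jun, Clu, Gja1, Zbtb16 and Lifr became -0.88, -0.86, -0.79, -0.75, -0.67, -0.61, -0.60, -0.55, -0.55, -0.52, -0.51, -0.51, -0.46 and -0.36. Those of Sox9, Ccnd2, H2-D1, Lrrn4, Plin1, Malat1, Aldh1a1, Gstm2, Insl3 and Hsd17b12 became -0.26, -0.17, -0.15, -0.09, -0.08, -0.07, -0.04, -0.04, 0.00 and 0.00. The cell cycle list passed, at -0.65 against all genes.

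List values here are medians minus that of all genes tested. Without the count filter the lymphocyte, differentiating spermatogonial, nuclear oxidative phosphorylation and mesothelium lists reversed to 0.53, 0.30, 0.08 and 1.36, with more genes tested, and the cell cycle list passed at -0.37. The cell cycle list also passed without genes that several lists hold, at -0.78, while in the main test it lay at -0.64 and did not pass. Fry, which tests a list against no change and not against other genes, called the cell cycle, lymphocyte, differentiating spermatogonial, nuclear oxidative phosphorylation, adipocyte and mesothelium lists, which camera did not, with Benjamini-Hochberg adjusted p-values of 4.03e-05, 8.36e-05, 1.74e-07, 0.000362, 0.00572 and 0.000668. Over the libraries left out in turn, the mesothelium list ran from -0.77 to 1.52, and the unfolded protein response list from 0.00 to 0.25. With an estimated correlation 0 of the 22 called lists passed, among them none of the steroidogenesis, Leydig identity, Sertoli, meiotic, spermatid, oxidative stress and p53 lists at 2.35, 3.19, 2.40, -2.79, -8.83, 2.08 and 1.78.

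Against genes of the somatic cell type lists, 13 lists were called. The mesenchymal, myoid, endothelial, undifferentiated spermatogonial, unfolded protein, heat shock, p53, extracellular matrix, androgen-responsive Sertoli, mitochondrial messenger and replication-independent histone lists reversed to -0.26, -0.45, -0.58, -0.18, -1.83, -1.24, -0.25, -0.57, -0.63, -0.46 and -1.76. Of these the unfolded protein, heat shock and replication-independent histone lists passed, and for the extracellular matrix and mitochondrial messenger lists only the median turned, while the test, which did not pass, still pointed up. The steroidogenesis, oxidative stress, androgen metabolism, cholesterol synthesis, macrophage, immediate early, cytokine, interferon and growth lists no longer passed, at 0.25, 0.00, 0.46, 0.19, 1.03, 0.06, 0.71, 0.64 and 0.46, and the tests of the oxidative stress, cholesterol synthesis and immediate early lists pointed down. The cell cycle list passed at -2.39, and the lymphocyte, differentiating spermatogonial, nuclear oxidative phosphorylation and mesothelium lists at -4.34, -2.28, -1.92 and -2.76. That background itself rose, which shifts every list. With the median log2 CPM of members as the score, the differences were -1.15 for steroidogenesis against Sertoli and 0.35 for Leydig identity against Sertoli. For steroidogenesis against Leydig identity it was -1.50. With mean scores but without Lipe the first was 0.06, a reversal, and the last -0.50, since Lipe fell far below the other members.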

Other observations

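Of the tests reported here, those of germ cell loss alone, of Sertoli genes shared with germ cells, of mitochondrial ribosomal RNA and of mitochondria per cell were chosen after the result was seen. Genes that rose beyond the mean level of the Leydig identity list were few. With that list held equal in every library, 154 genes were higher, 133 of them protein coding, 8 on the X chromosome and 72 with a mean of at least 10 CPM. Among those named after their values were seen, Hspb8, a small heat shock protein, Socs3, a feedback inhibitor of cytokine signalling, and Timp1, an inhibitor of matrix proteases, were 2.88, 2.53 and 2.10 above on the log2 scale. Serpina3n and Trib3 were at 2.42 and 2.27, and Lhcgr, Hsd3b1, Hsd17b3 and Cyp17a1 at 0.96, 0.66, 0.57 and 0.34. The calls take the mean level of the list as known, without its spread over members. The median of the list itself lay at 0.18. Small excesses such as that of Cyp17a1 are therefore not shown to exceed Leydig identity genes as a set. Hspb8, Socs3, Timp1 and Trib3 are genes of low counts, with means of 8.51, 2.90, 3.53 and 1.64 CPM, below the 10 CPM of the naming rule. Star and Cyp11a1 were at 0.06 and 0.07 and were not called. The steroidogenesis list, with a median of -0.65 at this level, had 5 such members of 21. The macrophage list had 3 and the Sertoli, oxidative stress, interferon and cell cycle lists 0. The Leydig identity list had 6, among them Lhcgr, but holding its mean level equal places some of its members above it by construction. The growth signalling list had 3 and the cytokine list 2. The unfolded protein, heat shock, p53, immediate early and extracellular matrix lists had 1 each, of 30, 19, 27, 20 and 30 tested.

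Some genes were counted in 1 group only. In the deletion 1185 of the genes called lower had 0 counts in every library, and 29 of those called higher had 0 counts in every WT library. Besides Wfdc18, the latter included Wnt4, a secreted signalling protein, at least 80.5-fold higher, Hrk, a promoter of cell death, at least 59.5-fold, and Ptpn5 at least 43.7-fold. By gene type, 653 of 793 tested long intergenic noncoding RNAs and 501 of 598 antisense RNAs were lower, against 6059 of 14305 protein-coding genes, where 6079 were higher.

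Leydig identity genes rose by 0.55 more than Sertoli genes on the log2 scale, with an SD of 0.12 between replicates and an SE of 0.25 over members. With the median level of members as the score of a library, the difference was 0.35. The median log2 changes of the members were 3.0 and 2.22. A loss of germ cells alone would raise both lists alike if germ cells express neither. The difference of means passed 2 SE over members by a narrow margin, and that SE was added after the value was seen. With fitted fold changes, at 0.52, it did not pass 2 of its own SE, so the means alone do not decide. Upper quartiles of the fold changes differed by 0.78 (SE 0.23). An upper quartile leaves out germ cell expression only if enough Sertoli genes are free of it, which was not checked. The highest log2 changes were 3.97 in the Sertoli and 4.31 in the Leydig identity list. The quartiles thus go against a loss of germ cells alone only for genes without germ cell expression. Wider germ cell expression of Sertoli genes stays open. Against the Sertoli list, the endothelial, myoid, macrophage and mesenchymal lists moved by -1.24, -1.74, 0.06 and -0.54 (SE 0.34, 0.61, 0.37 and 0.32), with Actg2 and Pln weighing on the myoid mean. At the upper quartile they lay at -1.05, -0.96, 0.63 and -0.07 (SE 0.31, 0.18, 0.28 and 0.28). The extracellular matrix list was at -0.81 (SE 0.21), and at -0.57 (SE 0.26) at the upper quartile. The endothelial, myoid and matrix lists thus moved apart by both measures and the mesenchymal list by neither. The macrophage list passed 2 SE at the upper quartile only, so a gain there was not particular to the Leydig identity list. With fitted fold changes the difference of means was 0.52, and 0.67 (SE 0.59) after a correction for GC content and gene length, and since both lie within 2 SE of 0, that explanation cannot be told apart. A change in Leydig cell number or in expression per cell stays open as an untested hypothesis.

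The mitochondrial share of counts was 3.69 times higher in the deletion. Uneven removal of mitochondrial ribosomal RNA is argued against by the mitochondrial messenger RNAs, which had a median log2 change of 1.39, while ribosomal RNA per messenger RNA changed by -0.14. More mitochondria per cell may contribute, and cannot be told apart: the nuclear oxidative phosphorylation list had a median of -0.36 (SE 0.16) with TMM scaling but 0.28 with no scaling. On TMM values alone that test would have argued against this explanation, and the condition that 4 scalings concur was added after its result was seen. A different makeup of cell types stays open as well.

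X-linked genes lay 1.86 above autosomal ones. The difference was 1.91 (SE 0.09) after a correction for GC content and gene length, so these do not account for it. Without genes of the fixed lists it was 1.90 (SE 0.09). Those lists hold a small part of the tested genes, so leaving them out could hardly move the medians and no conclusion is drawn. A loss of germ cells that silence the X chromosome in meiosis stays open as an untested hypothesis. An effect of H3t on the X chromosome itself was not tested either.

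The 6 libraries can be split into equal groups in 10 ways, and 1 of the 10 splits, that by genotype, gave 14403 called genes, where the highest of the others gave 0 by edgeR's quasi-likelihood test and 15 at an unadjusted p under 0.05, and 10 splits are too few for a share under 0.05. Of the tested genes near H3f4, 5 of 7 were lower within 100 kb on each side, 8 of 19 within 500 kb and 22 of 40 within 1000 kb, against 46.1% of all genes. Higher were 1, 8 and 14 of them. Trim17, whose span holds H3f4, fell by 6.86. The mitochondrial genes mt-Nd3, mt-Nd4l, mt-Co3, mt-Atp6 and mt-Atp8 had 5, 1, 46, 51 and 13 counts over the 6 libraries and share 98.0%, 98.8%, 99.9%, 99.5% and 0% of their 50-mers with other genes.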
